A study of Mus musculus with 82 samples.

How the data were processed

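Gene expression was measured in naive CD4 T cells of inbred mouse strains on Affymetrix ST1.0 arrays, which read many short probes per transcript and combine them into 1 value per probe set. Per the labels' protocols, the cells were sorted from spleen as positive for CD3, CD4 and CD62L and negative for markers of other blood cells and for CD25, from pools of male mice. The labels give an age of 6 weeks, whereas the series description gives 5 weeks. The series description also speaks of bone marrow granulocytes, where the cell type was taken from the labels, and of a number of probes other than the 24922 found. Per the submitters' processing notes, RMA and Affymetrix Power Tools were used, with versions, probe annotation and any filter of probe sets not given in the sources used here. The deposited table held 1 linear intensity per probe set and array, normalized by the authors, for 24922 probe sets on 82 arrays, with array medians from 102 to 142. Values were taken to log2 with no further normalization and no filter.

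Samples were put in 40 groups by strain, from the array titles and the background label. A total of 38 groups held 2 arrays, C57BL/6J held 5 and SWR/J held 1. The labels name 39 genetic backgrounds. Arrays titled C57BR carry the background label CBA/CaJ and arrays titled DBA2 carry DBA/1LacJ. These arrays were kept as groups of their own, called C57BR-titled and DBA2-titled. Each array is a pool of mice that the series describes as a biological replicate, and p-values measure the spread between such pools.

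Gene symbols came from the platform annotation paired with the probe sets. A total of 21425 probe sets had 1 symbol, 1399 had several and 2098 had none. Only probe sets with 1 symbol were named. Gene order, used for neighbouring genes alone, came from the GRCm38.p6 assembly, and no genome build is given for the deposited values, so no coordinates are given.

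Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 82 arrays (lmFit, eBayes), which left 42 residual degrees of freedom, to which the shared prior added 8.09. Variation between strains was tested with the moderated F-test, and pairs of groups with contrasts. P-values were adjusted by Benjamini and Hochberg over all probe sets, with a threshold of 0.05. The SD of strain means and the intraclass correlation, the share of variance that lies between strains, were computed per probe set. The 4 strains derived from mouse subspecies other than M. m. domesticus (CAST/EiJ, PWD/PHJ, MSM/Ms and JF1/Ms) were compared with the other 36 by limma on strain means, so that the strain was the replicate. Probe sets differing between C57BL/6J and nearly all strains were those past the threshold the same way in at least 35 of 38 contrasts, set against 20 simulated data sets without strain effects in which the same reference arrays were shared.

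A total of 30 gene lists covered T cell states, interferon and antigen presentation genes, receptor and signalling families, housekeeping processes, markers of other cell types, sex and genes with known null alleles. The probe set with the highest mean stood for each gene. For variation between strains, the median SD of strain means was set against 10000 random lists of the same size matched on mean expression. The median intraclass correlation was tested likewise. This two-sided test draws random genes and is called a permutation test where lists are described. It takes the genes of a list as independent, so genes that vary together make its p-values too small. For contrasts, limma's camera was used with a preset correlation of 0.01 and again with an estimated correlation. Named genes had 1 symbol, an established name and a highest strain mean above the median of all values. Each was read from its most significant probe set, which can differ between comparisons. For variation between strains, these were the 25 with the largest SD of strain means among those past the threshold with an intraclass correlation of at least 0.8. For the subspecies comparison they were the 12 largest differences each way where all 4 strains lay on 1 side of the mean of the others. For NOD/ShiLtJ they were the 12 largest changes shared by both contrasts and the 6 largest in each alone. For each closely related pair they were the 10 largest changes, and for C57BL/6J against nearly all strains up to 20. Up to 4 members past the threshold were named per list, and for variation between strains list members with wide ranges were named after their values were seen. The grouping, tests, lists, naming rule and most alternative settings were fixed before the data were examined.

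The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40 percent of probe sets, 1 probe set per symbol, a trended and robust prior, an offset of 32 before log2, the B cell list mean as a covariate, the replicate number as a block, array weights, an added 2-fold minimum and leaving out each array in turn. The models were tested on simulated data with 200 changed probe sets among 24922. For NOD/ShiLtJ against NOR/LtJ, 19.4 percent of changes of 0.5 on the log2 scale were recovered, 94 percent of changes of 1 and 100 percent of changes of 2, with 11 unchanged probe sets called. For variation between strains, 79.1 percent of probe sets with an SD of strain means of 0.2 were recovered and 98.5 percent of those at 0.4. The simulated noise was drawn independently for each probe set, without shifts shared by a whole array. Recovery and false calls on the real arrays can therefore differ. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.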

Results

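The data comprised 82 arrays of sorted naive CD4 T cells from 40 strain groups, with 24922 probe sets per array. Of the 81 arrays with a partner of the same strain, 62 correlated best with an array of that strain. The median correlation was 0.995 between arrays of the same strain and 0.987 between strains. Array medians ran from 102 to 142, with a median of 113.

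T cell genes differed in their range between strains. Cd3e, a chain of the T cell receptor complex, ranged in intensity from 5481 in DDY/JclSidSeyFrkJ to 8145 in RIIIS/J, Cd4 from 2786 in BPL/1J to 5668 in NZB/BINJ, Cd8b1 from 206 in CAST/EiJ to 897 in RIIIS/J, and Foxp3, the regulatory T cell transcription factor, from 248 in JF1/Ms to 926 in 129S1/SvImJ. In other-cell markers, 1 array of PL/J and 1 of A/J stood apart. The B cell list mean was 8.57 on replicate 2 of PL/J against 6.20 on replicate 1, and 7.39 on replicate 2 of A/J against 6.25 on replicate 1. On the same PL/J array the neutrophil list was higher by 1.46, the erythroid list by 1.16 and the myeloid list by 1.10, and on the A/J array the erythroid list was higher by 1.15.

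**Figure D1:**
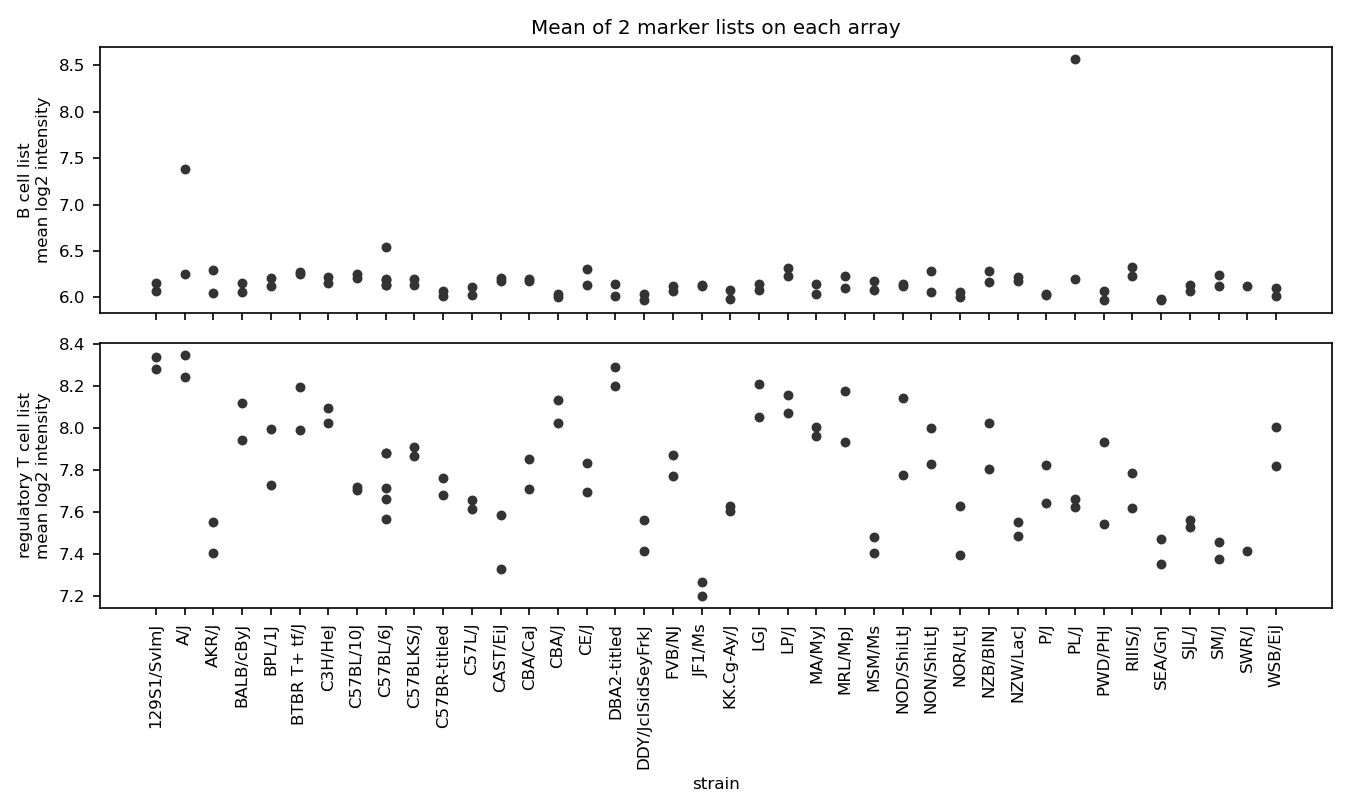
Mean log2 intensity of the B cell list (upper panel) and the regulatory T cell list (lower panel) on each array, by strain. The B cell list reached 8.57 on 1 array of PL/J and 7.39 on 1 array of A/J, while the regulatory T cell list differed between strains with an intraclass correlation of 0.827.

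The first comparison asked which genes differed between strains. Several genes were high in a few strains and low in most others. Gdpd3, which encodes a glycerophosphodiester phosphodiesterase, reached an intensity of 6380 in RIIIS/J against a strain median of 76.8 (SD of strain means 2.49, replicate SD 0.16 on the log2 scale). Aass, an enzyme of lysine breakdown, reached 4592 in MA/MyJ against a median of 28.5. A probe set annotated to Kcnma1, a calcium-activated potassium channel gene, reached 5523 in AKR/J against a median of 23.8. Whether its probes read Kcnma1 was not checked, as no probe sequences were at hand. Other genes were low in a few strains, where reduced expression was not tested against probe mismatches. The interferon-induced gene Samd9l stood at 12.6 in JF1/Ms against a median of 1159, the membrane protein gene Ms4a4b at 47.4 in WSB/EiJ against 3149, Dapl1 at 67.9 in PWD/PHJ against 5755, and Ly6e, a surface protein of the Ly6 family, at 86.3 in CAST/EiJ against 5184. Trim12a, of the tripartite motif family, had an intensity below the median of all values in 26 strains and 1617 in MA/MyJ. Ctse, which encodes the protease cathepsin E, ranged from 480 in C57L/J to 6683 in RIIIS/J.

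In the limma F-test, 11853 of 24922 probe sets (47.6 percent), from 9147 genes, differed between strains. Among the 14512 probe sets whose highest strain mean lay above the median of all values, 72.6 percent did. A strain range of at least 2-fold was seen in 4387 probe sets and one of at least 8-fold in 270. Over all probe sets the median SD of strain means was 0.143 and the median replicate SD 0.160 on the log2 scale, and the intraclass correlation was at least 0.8 in 1317. The 25 genes named by rule all had an adjusted p of 4.92e-15 or less. They included the interferon-related genes Trim30d, Ifi208, Ifi214, Ifi27l2a, Ifitm2 and Slfn8, the receptor and ligand genes Klrd1, H60b, Tnfrsf26 and Ryk, the inflammasome sensor gene Nlrp1a, the peptide transporter gene Slc15a2 and the T cell receptor segment Trav14-1. Also among them were Zfp979, Vmn2r96 and Lyz2. Lyz2, a lysozyme gene of myeloid cells, stood at 1563 in CAST/EiJ against a median of 50.3. With array weights the count rose to 18087. In groups of 2 arrays both had the same weight, so the weights cannot single out a poor array there.

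**Figure D2:**
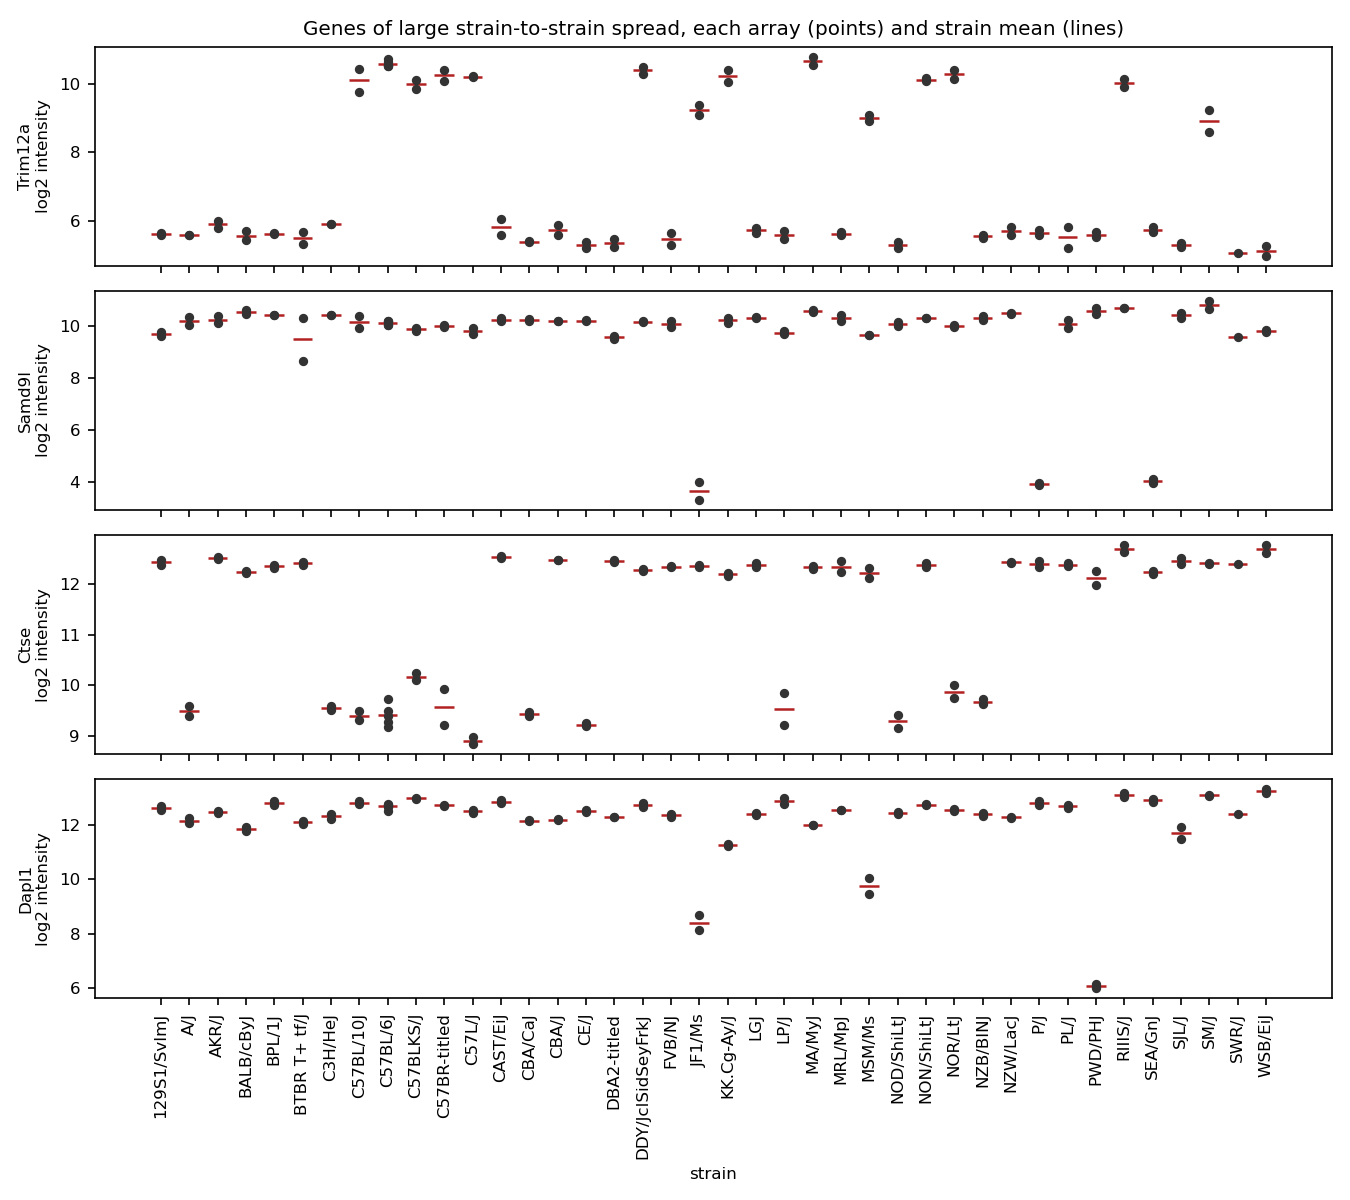
Log2 intensity of 4 genes on each array (points) with the strain mean (lines), by strain. Trim12a and Ctse fall into a high and a low set of strains, whereas Samd9l and Dapl1 are low in few strains, down to an intensity of 12.6 in JF1/Ms for Samd9l and 67.9 in PWD/PHJ for Dapl1.

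Interferon-related lists varied between strains more than other genes of like expression. All 33 measured genes of the type I interferon response passed the F-test over all probe sets, as did 33 adjusted over the list alone, with a median SD of strain means of 0.478 against 0.163 in matched random lists (adjusted p = 0.000545, permutation test). The same adjusted p, set by the smallest value the permutations can give, was reached by the guanylate-binding proteins and immunity-related GTPases (10 of 10, 10 adjusted over the list alone, median SD 0.555), the Ifi200 family (6 of 7, 7 adjusted over the list alone, 0.461), regulatory T cell genes (16 of 17, 17 adjusted over the list alone, 0.442) and genes of activated or memory T cells (31 of 35, 32 adjusted over the list alone, 0.306). Within these lists, Iigp1 ranged from 49.3 in CAST/EiJ to 614 in SJL/J, Nrp1 from 68.9 in SEA/GnJ to 1305 in MSM/Ms, and Cd44, an adhesion receptor, from 128 in BTBR T+ tf/J to 779 in PWD/PHJ. Genes that define naive T cells passed the test in 26 of 26 cases (26 adjusted over the list alone), with an SD of 0.154 against the matched 0.157 (adjusted p = 0.839, permutation test), but with a median intraclass correlation of 0.683 above the matched 0.537 (adjusted p = 0.0025, permutation test). T cell receptor signalling genes passed in 32 of 32 cases (32 adjusted over the list alone), with an SD of 0.162 against 0.164 (adjusted p = 0.839, permutation test) and an intraclass correlation of 0.588 against 0.523 (adjusted p = 0.17, permutation test).

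Further lists also lay above their matched random lists. The Gimap family of small GTPases (8 of 8 genes past the threshold, 8 adjusted over the list alone) had an adjusted p of 0.00353, MHC class I genes (14 of 14, 14 adjusted over the list alone) one of 0.0226, chemokine receptors and integrins (21 of 24, 22 adjusted over the list alone) one of 0.000545, and cytokine receptors (24 of 30, 24 adjusted over the list alone) one of 0.022 in the permutation test. Immediate early and stress response genes (28 of 33, 30 adjusted over the list alone) had 0.000545, cell cycle genes (27 of 35, 30 adjusted over the list alone) 0.002, glutathione and xenobiotic metabolism genes (24 of 31, 24 adjusted over the list alone) 0.00185, and the Ly6 family (6 of 9, 6 adjusted over the list alone) 0.014 in that permutation test. Genes with known strain-specific null or deficient alleles (11 of 16, 12 adjusted over the list alone) had an adjusted p of 0.001 in the permutation test, and the sex list (3 of 5, 3 adjusted over the list alone) one of 0.0192. Of the lists in this paragraph above their matched lists in SD, the sex list did not pass in its intraclass correlation (adjusted p = 0.492, permutation test). Lists not past the threshold were the Slam family (7 of 9, 7 adjusted over the list alone, adjusted p = 0.0895 in the permutation test), killer cell lectin-like receptors (6 of 21, 6 adjusted over the list alone, 0.215), ribosomal proteins (42 of 46, 43 adjusted over the list alone, 0.113), oxidative phosphorylation (44 of 50, 46 adjusted over the list alone, 0.104), platelet genes (2 of 8, 2 adjusted over the list alone, 0.45) and plasmacytoid or dendritic cell genes (4 of 12, 4 adjusted over the list alone, 0.541).

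The lists of 6 other cell types and of MHC class II lay above their matched lists in the SD of strain means, and of these CD8 T cells alone did so in the intraclass correlation. The B cell list had a median SD of 0.271, above its matched 0.128 (adjusted p = 0.000545, permutation test), but only 3 of 21 genes passed the F-test (2 adjusted over the list alone), and the list mean had an intraclass correlation of 0.112. MHC class II genes (4 of 10, 4 adjusted over the list alone, SD 0.405), CD8 T cell genes (5 of 8, 5 adjusted over the list alone, 0.358) and neutrophil genes (2 of 16, 2 adjusted over the list alone, 0.184) had the same adjusted p of 0.000545 in the permutation test. Natural killer cell genes (5 of 13, 5 adjusted over the list alone) had 0.00353, myeloid genes (7 of 20, 7 adjusted over the list alone) 0.002 and erythroid genes (3 of 7, 3 adjusted over the list alone) 0.0145 in that permutation test. For the median intraclass correlation of the genes, the adjusted p in the permutation test was 0.0409 for CD8 T cells, 0.178 for natural killer cells, 0.499 for B cells and for MHC class II, 0.492 for neutrophils and for myeloid cells and 0.795 for erythroid cells. The CD8 list mean, with Klrd1 and Cd8b1 among its members, had an intraclass correlation of 0.71, the neutrophil list mean one of 0.233 and the myeloid list mean one of 0.333. Those of T cell lists were 0.827 for regulatory T cells, 0.881 for the interferon response and 0.737 for activated T cells.

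The second comparison set each strain against C57BL/6J, the strain of the mouse reference genome. Over 38 strains, the median number of differing probe sets was 1539. The smallest numbers were 362 probe sets in C57BR-titled mice, 415 in C57BLKS/J, 434 in C57L/J and 620 in C57BL/10J. The largest numbers were 5908 in PL/J and 5239 in CAST/EiJ. A majority of the called probe sets was lower than in C57BL/6J in most strains, with a median of 70.1 percent lower (48.9 in 129S1/SvImJ to 83.9 in FVB/NJ). The median was 63.6 percent lower after centring each array on its median and 52.5 percent after quantile normalization, which by itself evens out higher and lower calls.

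In 37 of 38 strains the count moved by over 1.5 times on leaving out at least 1 array. All 37 did so without 1 of their own arrays, which leaves the strain 1 array and by itself lowers power. Lost power does not account for a count that rose, as in CE/J, MRL/MpJ and C57BL/10J without their replicate 1. In these strains the count fell without the other array, so it rested largely on single arrays. Without 1 array of C57BL/6J, the counts of 6 strains moved by over 1.5 times. Without replicate 2, the PL/J count was 1956. CAST/EiJ gave 2390 without its replicate 2, 3122 without its replicate 3 and 8933 without replicate 5 of C57BL/6J, when 39.5 percent were lower against 64.9 percent with all arrays. C57BR-titled mice gave 200 and 198 without replicate 1 and replicate 2, C57BLKS/J 156 and 176, and C57L/J 170 without replicate 2.

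**Figure D3:**
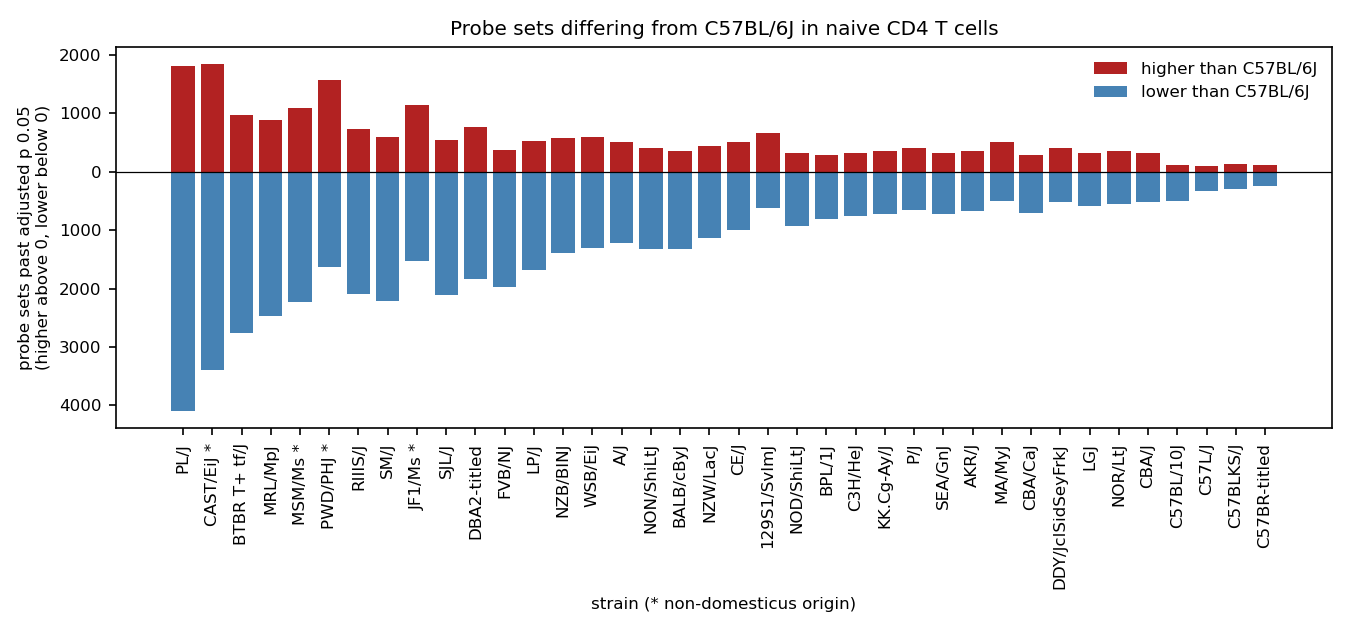
Number of probe sets past an adjusted p of 0.05 in each strain against C57BL/6J, higher drawn above 0 and lower below 0, with the strains of non-domesticus origin marked by an asterisk. Totals run from 362 in C57BR-titled mice to 5908 in PL/J, where 1956 were left without replicate 2.

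Few genes set C57BL/6J apart from nearly all strains. A total of 13 probe sets differed the same way from at least 35 of 38 strains, 11 of them higher in C57BL/6J and 2 lower. In each of 20 simulated data sets with the same shared reference arrays the count was 0. As these held no strain effects, they speak to noise between replicates alone. Whether another strain as reference would give as many was not tested, nor were probe mismatches. Rell1 and Entpd4, a nucleotide-hydrolysing enzyme gene, were higher in C57BL/6J than in all 38 strains and lay above the mean of all other strains by 0.90 and 0.64 on the log2 scale. Pttg1, the securin gene of chromosome separation, and Eps8l1 were higher than in 36 strains each and lay 1.30 and 1.09 above that mean. Rab6b (1.94 from that mean), Chn2 (1.45) and Cfap74 (0.81) were higher against 35 strains each, Chn2 and Cfap74 being lower against 1, and Scpep1, a serine carboxypeptidase gene, was lower against 35 (-1.31). Entpd4, Chn2 and Cfap74 fell below the required 35 strains after quantile normalization and after median centring, and Cfap74 also with the replicate block and with array weights. With the C57BL/6J arrays split into 2 and 3 each serving every other strain in alphabetical order, a division added after the data were seen, 8 probe sets met the criterion, all of them among the 13. Of 16 probe sets found after quantile normalization, 43.8 percent were lower in C57BL/6J against 15.4 percent of the 13.

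The third comparison set the 4 strains of non-domesticus origin against the other 36. Single genes of natural killer receptors and of the interferon-induced transmembrane family were higher in the 4 strains on average. Klrd1, which encodes the CD94 chain of natural killer receptors, was higher by 3.34 ± 0.50 (SE, log2), Klrb1f by 3.12 ± 0.29, Ifitm2 by 3.69 ± 0.43 and Ifitm1 by 2.17 ± 0.29, although Ifitm1 in CAST/EiJ (4.78) lay close to the mean of the other strains (4.66). Nt5e, the adenosine-producing ectoenzyme CD73, was higher by 2.32 ± 0.36. The regulatory T cell genes Izumo1r (folate receptor family), at -2.90 ± 0.15, and Gpr83, at -2.79 ± 0.23, were lower. So were Clec2i, a ligand of natural killer receptors, at -2.38 ± 0.23 and the MHC class I gene H2-Q4 at -2.90 ± 0.44. For the lower genes and lists of this comparison, reduced expression was not tested against probe mismatches. Ifitm2 was read here from another probe set than for variation between strains, whose difference by origin is not given here. Of the 24 genes named for this comparison, 21 were read from the probe set with the highest mean for their symbol.

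In limma on strain means, 2176 probe sets passed the threshold, 1237 higher and 939 lower in the 4 strains, and 216 differed at least 2-fold. Also higher were Cldn10 (2.81), Nebl (2.81), Clstn3 (2.05), Lyz1 (1.86), Btbd3 (1.84), Dmbt1 (1.82, adjusted p = 0.000976) and Plxdc2 (1.81). Also lower were Lypd6b (-2.32), the tetraspanin gene Cd9 (-2.18), the RNA sensor gene Tlr7 (-2.12), the cadherin gene Celsr1 (-2.01), Mrfap1 (-1.79), the ubiquitin ligase gene Rnf7 (-1.73), Gbp8 (-1.70, adjusted p = 0.0174) and Oas1c (-1.66). Gbp8 lost its call without MSM/Ms (adjusted p = 0.0815) and without PWD/PHJ (adjusted p = 0.064).

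No gene list passed the threshold in the 4 strains once the correlation between genes was estimated. With the preset correlation, regulatory T cell genes (adjusted p = 0.00776), MHC class I genes (2e-04), T cell receptor signalling genes (0.0372) and ribosomal protein genes (8.44e-05) were lower, and each had an adjusted p = 0.802 with an estimated correlation. Of 17 regulatory T cell genes, Izumo1r and Gpr83 fell and Nrp1 rose (1.40), with 4 past the threshold adjusted over the list alone. Of 14 MHC class I genes, H2-Q4, Tap1 (-0.52), Psmb9 (-0.51) and H2-M3 (-0.34) fell, with 5 past the threshold adjusted over the list alone. Of 46 ribosomal protein genes, 8 fell, such as Rps19 (-1.12), and 1 rose (Rpl7, 0.97), with 9 adjusted over the list alone. Of 32 receptor signalling genes, 8 fell, among them Txk (-0.56) and Cd3g (-0.51), and 3 rose, among them Pag1 (0.42), with 12 adjusted over the list alone. Of 33 interferon response genes, Mx1, an antiviral GTPase gene, rose (1.33), and Oas2 (-1.52), Ifit2 (-1.24), Dhx58 (-0.68) and Ifi27 (-0.39) fell, with 12 adjusted over the list alone. The list's median (0.02) was positive while its mean (-0.08) and test were negative. Among 35 genes of activated or memory T cells 4 rose, namely Cd44 (1.39), Anxa2 (1.05), Cd69 (0.52) and Cxcr6 (0.48), and 4 passed adjusted over the list alone, with a median (-0.03) and test below 0 and a mean (0.08) above 0. Of 30 cytokine receptor genes 6 rose, such as Il10ra (1.35) and Il18r1 (0.75), and 1 fell, with 9 adjusted over the list alone. Of 20 myeloid genes Lyz2 (2.91) and Lyz1 alone passed, of 21 killer cell lectin-like receptor genes Klrd1, Klrb1f and Klrk1 (0.63) rose and Clec2i and Clec2d (-0.61) fell, with 5 adjusted over the list alone (camera adjusted p = 0.771, and adjusted p = 0.877 with an estimated correlation), and of 21 B cell genes 0 did in limma, also 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05.

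The fourth comparison set NOD/ShiLtJ, which develops autoimmune diabetes, against its diabetes-resistant relatives NOR/LtJ and NON/ShiLtJ. Trim12a and Trim30d, of the tripartite motif family, were lower in NOD/ShiLtJ than in both relatives. Trim12a stood at -4.97 ± 0.18 (SE, log2) against NOR/LtJ and at -4.82 ± 0.18 against NON/ShiLtJ, and Trim30d at -2.41 ± 0.23 and -2.53 ± 0.23. Low Trim12a was not particular to NOD/ShiLtJ (5.20 and 5.39 on its arrays). Many other strains stood near it, such as 129S1/SvImJ (5.65 and 5.57) and A/J (5.59 and 5.59), whereas C57BL/6J replicate 1 stood at 10.64. For genes lower in NOD/ShiLtJ, reduced expression was not tested against probe mismatches. Trim34a (-0.88 and -0.75) and Pgap2 (-1.06 and -0.94) were lower, as were Desi1 (-1.44 and -1.51) and Pagr1a (-1.67 and -0.94). Cxcr2, a chemokine receptor gene of neutrophils, was higher by 3.16 ± 0.23 against NOR/LtJ and by 0.83 ± 0.23 against NON/ShiLtJ, while the other 15 measured neutrophil genes did not pass in either contrast. Ehd4 (0.89 and 0.75) and Sqor (0.78 and 0.78) were higher against both.

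**Figure D4:**
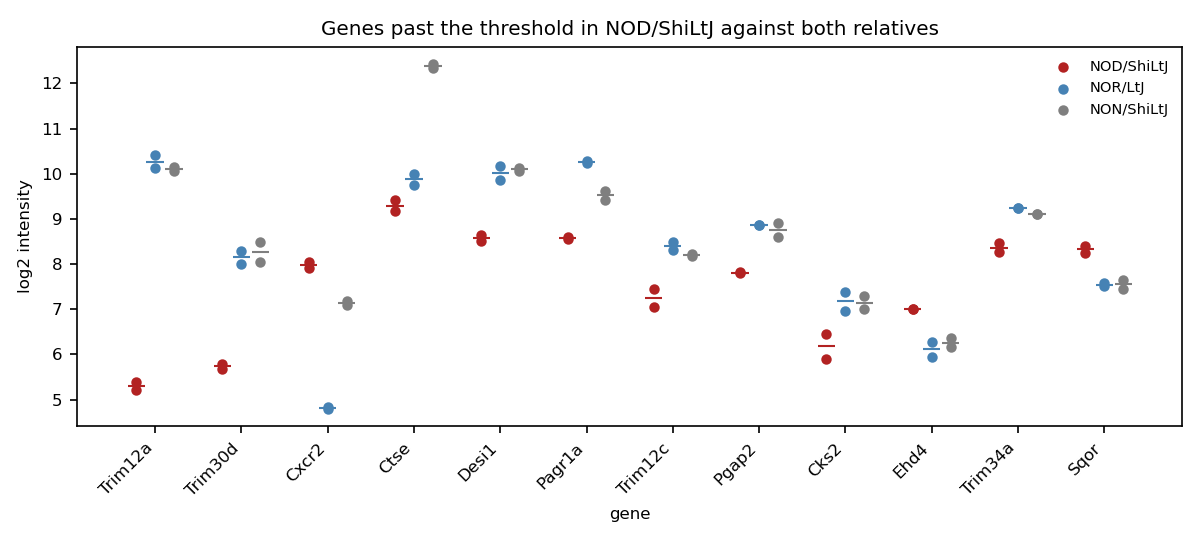
Log2 intensity of 12 genes that passed the threshold in the same direction in NOD/ShiLtJ against both relatives, for each array (points, 2 per strain) with strain means (lines). Trim12a lies 4.97 below NOR/LtJ on the log2 scale and Cxcr2 lies 3.16 above it.

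Against NOR/LtJ, 126 probe sets differed, 44 higher and 82 lower in NOD/ShiLtJ, and against NON/ShiLtJ 469 did, 237 higher and 232 lower (60.8 percent lower after median centring, 49.5 as deposited). With array weights the counts were 541 and 1124. In the same direction 26 probe sets passed in both, 5 higher and 21 lower, where independent lists would share 0.418 and 0.763, and simulated data without strain effects gave at most 0. In opposite directions 9 passed. With 1 NOD/ShiLtJ array for each relative, a division added after the data were seen, 17 passed in the same direction with replicate 1 against NOR/LtJ and replicate 2 against NON/ShiLtJ, where independent lists would share 0.13 higher and 0.27 lower, and 14 the other way round, where they would share 0.169 and 0.315. All of these were among the 26. In the contrast with NOR/LtJ alone, Zfp979 was higher (4.91), as was Arhgap18 (2.01), and Cpm (-2.62), the complement inhibitor gene Cd59a (-1.93), Fbxl21 (-1.79) and Pttg1 (-1.65) were lower. In the contrast with NON/ShiLtJ alone, H60b, a ligand of the NKG2D receptor (4.40), Atp8b4 (2.95) and Zfp931 (2.72) were higher, and Gdpd3 (-5.72), Slc15a2 (-4.03) and the metabolic kinase gene Pdk1 (-2.59) were lower. Whether the change differed between the relatives was not tested for these genes.

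In both contrasts the counts fell on leaving out any array of the pair, which leaves 1 array in that strain and by itself lowers power. Ctse (-0.59), Trim12c (-1.15), Cks2 (-0.998) and Sqor against NOR/LtJ, and Cxcr2, Trim12c, Cks2 (-0.97), Ehd4, Sqor and Pagr1a against NON/ShiLtJ, lost their calls on leaving out at least 1 array, and no named gene changed sign. After median centring Ctse, Trim12c, Cks2 and Sqor lost their calls against NOR/LtJ, and Cxcr2 and Trim12c did against NON/ShiLtJ. Quantile normalization ended the calls of Ctse against NOR/LtJ and of Cxcr2 against NON/ShiLtJ. Ctse also lost its call against NOR/LtJ with the B cell covariate, the replicate block and 1 probe set per symbol, and Trim12c lost its call against NON/ShiLtJ with the trended and robust prior and with the offset.

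With all arrays, interferon response genes were lower in NOD/ShiLtJ than in NOR/LtJ as a list and regulatory T cell genes higher, but no list call with an estimated correlation held on leaving out each array in turn. The interferon list had a median change of -0.29 (camera adjusted p = 1.19e-16, and adjusted p = 0.0315 with an estimated correlation). Within it Trim30d, Xaf1 (-1.19) and Ifi27 (-0.57) fell, 30 of 33 genes did not pass, and 5 passed adjusted over the list alone. The list mean was 7.83 and 8.14 on the 2 arrays of NOD/ShiLtJ and 8.37 and 8.33 on those of NOR/LtJ. The median change was -0.14 without NOD/ShiLtJ replicate 1 (adjusted p = 0.36 with an estimated correlation) and -0.45 without its replicate 2, and the adjusted p with an estimated correlation was 0.054 and 0.127 without NOR/LtJ replicate 1 and replicate 2. The regulatory T cell list had a median change of 0.61 (adjusted p = 9.59e-13, and adjusted p = 0.0269 with an estimated correlation), with Tnfrsf9 (0.75) the single gene of 17 past the threshold and 9 adjusted over the list alone. The list mean was 7.78 and 8.14 on the arrays of NOD/ShiLtJ and 7.63 and 7.40 on those of NOR/LtJ. The median change was 0.34 without NOD/ShiLtJ replicate 2 (adjusted p = 0.403 with an estimated correlation) and 0.38 without NOR/LtJ replicate 2 (adjusted p = 0.362 with an estimated correlation). MHC class I genes fell (median -0.16, adjusted p = 7.71e-06, and adjusted p = 0.0269 with an estimated correlation), with Tap1 (-0.43) the single gene of 14 past the threshold and 4 adjusted over the list alone. Their median was -0.085 without NOD/ShiLtJ replicate 1 (adjusted p = 0.203 with an estimated correlation) and -0.29 without its replicate 2, and the adjusted p with an estimated correlation was 0.054 and 0.0702 without NOR/LtJ replicate 1 and replicate 2. Chemokine receptors and integrins rose (median 0.13, adjusted p = 0.00083, and adjusted p = 0.0308 with an estimated correlation), with 0 of 24 past the threshold in limma, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05. This call was lost with either correlation without NOD/ShiLtJ replicate 2 (median 0.069, adjusted p = 0.0732 and 0.337) and without NOR/LtJ replicate 2 (adjusted p = 0.0741 and 0.362).

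Other list calls against NOR/LtJ were lost. These were activated T cells (higher, adjusted p = 0.0925 with an estimated correlation), guanylate-binding proteins (lower, adjusted p = 0.323 with an estimated correlation), ribosomal proteins (lower, adjusted p = 0.46 with an estimated correlation), oxidative phosphorylation (lower, adjusted p = 0.732 with an estimated correlation), cell cycle (higher, adjusted p = 0.275 with an estimated correlation), Gimap (lower, adjusted p = 0.546 with an estimated correlation), neutrophil (higher, adjusted p = 0.714 with an estimated correlation) and null-allele genes (lower by mean and test but with a median of 0.03, adjusted p = 0.141 with an estimated correlation).

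Against NON/ShiLtJ, the list of genes with known null or deficient alleles was lower (median -0.08, adjusted p = 0.00078, and adjusted p = 0.0167 with an estimated correlation). In it Ctse (-3.09), Trim30d and Klrd1 (-0.99) fell and Thy1 (0.61) rose, with 6 of 16 past the threshold adjusted over the list alone. The median was -0.034 without NOD/ShiLtJ replicate 1 (adjusted p = 0.0906 with an estimated correlation), -0.18 without its replicate 2, 0.0071 without NON/ShiLtJ replicate 1 (adjusted p = 0.0542 with an estimated correlation) and -0.18 without its replicate 2. Of 10 guanylate-binding protein and immunity-related GTPase genes, Gbp11 (-1.25), Gbp3 (-0.74), Gbp5 (-0.72) and Gbp4 (-0.57) fell and Gbp8 (1.60) rose, with 8 adjusted over the list alone, and the list had an adjusted p = 0.168 with an estimated correlation. The interferon response list had an adjusted p = 0.226 with an estimated correlation, with Trim30d and Eif2ak2 (-1.58) lower of 33 and 2 adjusted over the list alone. Single genes of activated T cells moved both ways, with S100a11 at -2.03 and Cd44 at 1.37, and 6 of 35 passed adjusted over the list alone. The chemokine receptor gene Cxcr4 was higher by 2.15 and the receptor gene Gpr183 stood at -0.99. Calls lost were MHC class I (adjusted p = 0.0795 with an estimated correlation), killer cell lectin-like receptors (adjusted p = 0.211 with an estimated correlation), Gimap (adjusted p = 0.211 with an estimated correlation) and cell cycle (adjusted p = 0.475 with an estimated correlation), all lower.

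The fifth comparison set closely related strains side by side. Among the genes named by rule, C57BL/6J and C57BL/10J differed most in Raver2, a splicing regulator gene, higher in C57BL/6J by 2.39 ± 0.13 (SE, log2). Next among them came the transcription factor gene Jun (-1.74 ± 0.49), Zbtb8a (1.71 ± 0.12), Mir15b (1.48 ± 0.41) and the chloride channel family gene Clic4 (1.40 ± 0.14). Then came Pttg1 (1.31 ± 0.10), the calcineurin regulator gene Rcan3 (1.19 ± 0.09), Snord47 (-1.13 ± 0.31), the histone gene H2bc3 (-1.12 ± 0.28) and Cd46 (1.10 ± 0.25). Jun, Mir15b, Snord47, H2bc3 and Cd46 each lost their call on leaving out at least 1 array. Jun, Mir15b and Snord47 also did after median centring, with the trended and robust prior and with array weights, Jun and Mir15b after quantile normalization, Mir15b and Snord47 with the replicate block, and H2bc3 with array weights. Without C57BL/10J replicate 3, H2bc3 stood at -0.25 and Snord47 at -0.64, whereas Mir15b stood at 1.43 to 1.51 where its call was lost. Cd46 did so without C57BL/10J replicate 3 (adjusted p = 0.37). A total of 620 probe sets passed, 504 of them higher in C57BL/6J. This count was not stable, with 145 without C57BL/10J replicate 3, 1395 without C57BL/10J replicate 1, 314 without C57BL/6J replicate 3, 330 after quantile normalization (44.8 percent lower in C57BL/6J against 18.7 as deposited), 171 after median centring (36.8 percent lower) and 108 with array weights.

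Among the genes named by rule, CBA/CaJ and CBA/J differed most in Slc15a2, a peptide transporter gene. Higher in CBA/CaJ were Slc15a2 (3.94 ± 0.37), Atp8b4 (3.00 ± 0.19), Gbp8 (2.50 ± 0.23), Cd72 (1.99 ± 0.30), Gpr174 (1.69 ± 0.22) and the glutamine transporter gene Slc1a5 (1.56 ± 0.14). Lower were H60b (-3.49 ± 0.29), Ctse (-3.04 ± 0.15), Coro2a (-2.56 ± 0.19) and Syt14 (-1.62 ± 0.18). A total of 90 probe sets passed, 32 higher and 58 lower in CBA/CaJ, with 56 without CBA/J replicate 1 and 217 with array weights. The 10 named genes passed on leaving out each array of the pair.

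Over the 703 pairs of the 38 strains with 2 arrays each, the median number of differing probe sets was 1155, from 50 to 6706. The 3 pairs among C57BL/10J, C57BLKS/J and C57L/J had 333 to 409, while C57BR-titled mice differed from these in 535, 418 and 50. Pairs within the CBA and C3H family had 90 to 214, and pairs among NOD/ShiLtJ and its relatives 126 to 721. Pairs with 1 strain of non-domesticus origin had a median of 2648 and pairs with none a median of 988.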

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

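Among the tests reported here, the effects of quantile normalization and of centring on the share of lower calls, the test of neighbouring genes and the test of other-cell RNA on 1 C57BL/6J array were chosen after the results were seen.

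Of 57 groups of 4 or 5 values tested, 13 held a value far from the others, where chance gives about 1 in 20 independent groups. Since 7 of the 13 values come from 1 array, the groups are not independent and the 13 cannot be set against that rate. Replicate 5 of C57BL/6J lay above the other 4 arrays in array median intensity (141.8), in the list means (log2) of B cells (6.55), natural killer cells (5.41), myeloid cells (6.49), erythroid cells (6.91) and plasmacytoid or dendritic cells (6.80), and in Jun (8.22). Entpd4 was lower on replicate 1 of C57BL/6J (9.96) than on the other 4 arrays. Within the 4 strains of non-domesticus origin, CAST/EiJ stood apart with Cldn10 at 6.45, Ifitm1 at 4.78 and Clstn3 at 9.92, and PWD/PHJ with Clec2i at 8.91 and Rnf7 at 7.47.

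On replicate 5 of C57BL/6J the tables argue against RNA of other cells as the source of the high marker lists. The 5 lists were higher there by a median of 0.41, but probe sets matched on mean level were higher by 0.41 too, and the shift beyond them had a median of -0.00229 (largest 0.10, for plasmacytoid or dendritic cell genes). Over all probe sets the median shift on this array was 0.234, and its interquartile range of 2.65 (log2) lay below those of the other 4 arrays. No biological explanation was tested.

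The excess of lower calls against C57BL/6J had a median of 70.1 percent and came to 60.3 percent without replicate 5 of C57BL/6J. The level of the arrays as its source cannot be told apart from others: after centring each array on its median it was 63.6 percent, with a majority lower in 34 of 38 strains, but from 53.6 percent without replicate 3 to 73.1 percent without replicate 5 of C57BL/6J. Nor can their spread be told apart, since quantile normalization, with 52.5 percent, evens out higher and lower calls by itself. Mismatches between probes designed on the reference genome and other strains' transcripts cannot be told apart from other sources. A prediction fixed before the data were examined put mismatches at over 60 percent lower in each of the 4 strains of non-domesticus origin. CAST/EiJ (64.9 percent) and MSM/Ms (67.2) met this with all arrays, while JF1/Ms (57.3) and PWD/PHJ (50.8) did not. Of the pooled calls, 60.9 percent were lower. Without replicate 5 of C57BL/6J no strain of the 4 met it. CAST/EiJ then had 39.5 percent lower, MSM/Ms 58.1, JF1/Ms 49.9 and PWD/PHJ 44.3. The outcome thus turned on 1 reference array. With all arrays, all 4 lay below the median of 70.1 percent over the strains. Against the other strains in place of C57BL/6J, 43.2 percent of the calls by origin were lower. In CAST/EiJ against PWD/PHJ 57.5 percent were lower, where the same prediction called for 40 to 60 percent. C57BL/10J, closely related to C57BL/6J, had 81.3 percent lower, and 63.2 after centring each array on its median. A high share was thus not limited to strains of distant origin. Real differences between strains remain among the open explanations, untested.

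Genes called between related strains were neighbours more than in permuted gene order in each of the 4 pairs tested. Against NON/ShiLtJ, 22 adjacent pairs were seen where permuted gene order gave a mean of 6.72 (permutation p = 1e-04, the smallest the permutations can give), and 15 of them had different name stems against a mean of 5.80 (permutation p = 0.001), which argues against shared probe sequence of related genes as the whole source. Against NOR/LtJ 5 pairs were seen against 0.406 (permutation p = 1e-04), but 1 had different name stems (permutation p = 0.3), so shared sequence among related genes cannot be told apart there with so few pairs. Between C57BL/6J and C57BL/10J 25 pairs were seen against 11 (permutation p = 3e-04), 17 of them with different name stems (permutation p = 0.02), and between CBA/CaJ and CBA/J 2 against 0.242 (permutation p = 0.03), both with different name stems (permutation p = 0.02). Stretches of the genome that differ between the strains are a candidate explanation, untested here. Calls were permuted over all 18519 genes with no filter on signal, so the test does not separate this from expressed genes lying together. Between C57BL/6J and C57BL/10J the longest run held the histone genes H1f2, H2bc3, H2ac4 and H1f1. Of these, H2bc3 moved from -1.12 to -0.25 without C57BL/10J replicate 3.

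For the difference by origin, 1 of 100 sets of 4 strains, the real one, gave 2176 probe sets. The highest of the other sets, drawn at random, gave 305. These values argue against a random choice of strains as the source, but 100 sets cannot exclude chance. The random sets were drawn without regard to kinship between strains, so the test does not separate origin from kinship in general. The B cell list mean had an intraclass correlation of 0.112, which is consistent with other cells carried through the sort on single arrays, where Cd79a reached 317 and Ms4a1 385 on 1 PL/J array although the sort excluded a B cell marker.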

How the results depend on the processing

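The removal of strains whose arrays correlated below 0.99, the removal of each C57BL/6J array in turn for the genes apart from nearly all strains, the division of the C57BL/6J and of the NOD/ShiLtJ arrays, centring combined with leaving out C57BL/6J arrays and the list tests without each array were tests chosen after the data were seen. No named gene changed sign under the settings run. Counts moved by over 1.5 times as follows, and apart from settings that by construction test fewer probe sets or add a minimum the cause was not tested. Quantile normalization gave 330 probe sets between C57BL/6J and C57BL/10J and median centring 171. With 1 probe set per symbol, there were 8 for C57BL/6J against nearly all strains and 83 for NOD/ShiLtJ against NOR/LtJ. Array weights gave 18087 for variation between strains, 541 against NOR/LtJ, 1124 against NON/ShiLtJ, 108 for C57BL/6J against C57BL/10J and 217 for the CBA pair. These weights were equal within each group of 2 arrays and so weighed strains, not single arrays, against each other there. A 2-fold minimum left 4387 for variation between strains, a median of 197 against C57BL/6J, 1 against nearly all strains, 216 by origin, 46 against NOR/LtJ, 95 against NON/ShiLtJ, 33 and 43. With the C57BL/6J arrays divided, 8 probe sets set this strain apart from nearly all strains, and with the NOD/ShiLtJ arrays divided 17 and 14 were shared by both relatives against 26. Centring each array gave medians of 877, 924.5, 916.5 and 948 against C57BL/6J without its replicates 1 to 4. Of 23 list calls in contrasts, 5 held with an estimated correlation, each of which was lost on leaving out at least 1 array. Leaving out arrays or strains gave 11390 to 13402 for variation between strains, a median of 1283.5 to 1861 against C57BL/6J, 11 to 19 against nearly all strains, 1484 (without MSM/Ms) to 2512 by origin, 77 to 89 against NOR/LtJ, 232 to 294 against NON/ShiLtJ, 145 to 1395 for C57BL/6J against C57BL/10J and 56 to 93 for the CBA pair. Where an arm kept 1 array, that array was assumed to vary like the other groups. The replicate numbers do not pair the samples, since over 703 pairs of strains the same-numbered arrays had correlations of deviations from -0.626 to 0.567 with a median of -0.00224. With the number as a replicate block the counts were 13096, a median of 1217.5, 13, 2237, 123, 504, 729 and 93 in the order given for the 2-fold minimum, all within 1.5 times. Signal over background limits the dim end, and with no background measure used here the lowest values, such as that of Samd9l, cannot be set against it.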

Other observations

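The comparison of groups with conflicting labels and the genes named here were chosen after the data were seen.

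Further genes of the immune and metabolic lists had wide ranges of intensity between strains. Gimap7, a GTPase of lymphocyte survival, ranged from 88.4 in CAST/EiJ to 1494 in JF1/Ms, whereas Gimap4 ranged from 1884 in CAST/EiJ to 5441 in BALB/cByJ. Among MHC class II genes, H2-Ob ranged from 89.1 in AKR/J to 1119 in BPL/1J and H2-DMa from 96.8 in WSB/EiJ to 1157 in RIIIS/J. Mgst2, a glutathione transferase gene, ranged from 143 in NZW/LacJ to 685 in NON/ShiLtJ, and Gzma, a granule protease gene, from 23.9 in CBA/J to 323 in CAST/EiJ. The intraclass correlations were 0.956 for Gimap7, 0.953 for H2-Ob, 0.929 for Mgst2 and 0.957 for Gzma.

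The arrays titled C57BR, which carry the background label CBA/CaJ, differed from C57L/J in 50 probe sets, the fewest of the 703 pairs, and from CBA/CaJ in 669, where CBA/CaJ differed from CBA/J in 90. Without each array of these 4 strains in turn, the number from CBA/CaJ was 377 (without C57BR-titled replicate 2) to 678, with 420 without CBA/CaJ replicate 2, and that from C57L/J 34 to 50. Trim12a was 10.24 in C57BR-titled arrays, 10.20 in C57L/J and 5.39 in CBA/CaJ. These values argue against CBA/CaJ as the strain of these arrays. The arrays titled DBA2, with the label DBA/1LacJ, differed from BTBR T+ tf/J in 461 probe sets, from C57BLKS/J in 490 and from MRL/MpJ in 550. Nnt, for which C57BL/6J is known to carry a deletion, had an intensity of 334 in C57BL/6J, 333 in DBA2-titled arrays and a median of 439 over the strains.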
